A study of Homo sapiens with 6 samples.

How the data were processed

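Guide abundance was measured in 6 samples from a pooled CRISPR screen in HAP1, a near-haploid human cell line derived from a chronic myeloid leukaemia. The samples were 2 of the library, 2 of parental cells and 2 of SETD2-mutant cells, and all columns of the count table were assigned to a sample by their names. Per the labels' protocols, the guide virus was added to each line at a multiplicity of infection of 0.7, and the infected cells were then divided into replicates and grown under puromycin for 12 doublings. Guides were amplified from genomic DNA and read as single-end reads of 75 bp. The labels do not say how the library samples were taken, and they name 1 SETD2-mutant genotype without a number of clones.

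The authors deposited raw counts per guide, and the values were whole numbers with no sign of scaling. Per the submitters' processing notes, MAGeCK and hg38 were used, with no role, version or settings given. The table held 71626 guides for 7093 genes and for 100 guides labelled dummyguide, whose meaning is not stated. Of the genes, 7007 had 10 guides, and 20 guide IDs were listed more than 1 time. Gene symbols were matched to a RefSeq table of the GRCh38 assembly, in which 6760 symbols were current, 316 matched by 1 synonym and 17 had no single match. Coordinates of genes are from that table, and the cut sites of single guides were not analysed here.

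Total counts were 38428425 and 34679351 in the library samples, 38197301 and 34003792 in the parental samples, and 25082426 and 33878004 in the SETD2-mutant samples. The median count per guide ranged from 284 to 466. Between replicates, the chi-square statistic per degree of freedom was 1.37 for the library, 14.1 for parental and 12.9 for SETD2-mutant samples, where counting error alone gives about 1, so in the cell lines the spread between replicates exceeded counting error.

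Guides with a mean library count of 30 or more were kept, a filter that does not look at either cell line. It kept 71470 guides and set aside 56. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood fits (glmQLFit, robust) of the 6 samples by group and glmQLFTest for each guide. Guides were combined to genes by robust rank aggregation (RRA), rebuilt from its published description because MAGeCK itself was not run, with a rank share limit of 0.25 and a null distribution from 4e+06 seeded draws for genes with 10 guides, 1e+06 for 3 to 9 guides and 1e+05 for larger genes. Genes with 3 or more guides were tested, 7090 in all. RRA is one-sided, so p-values were adjusted by Benjamini-Hochberg in each direction, and a gene is called depleted or enriched at an adjusted p below 0.05. The effect of a gene is the mean over its guides of the edgeR log2 fold change, with the standard error (SE) over guides.

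The 3 comparisons were SETD2-mutant against parental, parental against library and SETD2-mutant against library. Gene lists were tested on the mean over guides of log2 CPM (prior count 2) with limma 3.58.1, by camera with a correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists of each comparison. The 33 lists, the tests, the filter and the rule for named genes were chosen before the data were examined. The rule names the 6 measured H3K36 methyltransferases and the 12 depleted and 8 enriched genes with the lowest RRA p between the lines. It also names the 10 and 6 in each comparison with the library, and up to 4 members of each list. Among genes with the same lowest p, those with the larger absolute mean change were named. Some genes that this rule names are not reported here. Lists with under 3 measured genes were not tested: m6A writers and readers, mitochondrial ribosome and olfactory receptors (0 each), nonsense-mediated decay (2) and proteasome (1). Lists of nucleotide, mitochondrial and SAGA genes were added after their values were seen and are kept apart.

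The test was checked on simulated counts for SETD2-mutant against parental with 7090 genes. Each simulated guide carried a random part of the effect of its gene. The mean changes over guides were therefore smaller than the set effects. They were −1.51, −0.739, −0.383 and 0.76 for set effects of −2, −1, −0.5 and +1 with replicate spread alone. The rates that follow are listed by set effect. With replicate spread alone, RRA called 100% of genes changed by −2, 100% at −1, 70.0% at −0.5, 94.0% at +1 and 0 of 6890 unchanged genes. When guide differences shared by the replicates of a line were added (SD 0.459 per line), it called 84.0%, 12.0%, 0% and 12.0%, and 2 of 6890 unchanged genes. Summed counts per gene then called 3345 unchanged genes, 48.5%. A gene that was not called is therefore not shown to be unchanged. The replicates of a line share 1 transduction, so p-values measure only the spread between these samples.

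Alternatives covered the scaling (DESeq2 1.42.0 size factors, library totals, dummyguide counts), the test for each guide, the count filter, the aggregation of guides, the samples fitted, a replicate block, equal essential-gene dropout and the removal of each sample. Replicate numbers did not pair the samples, with correlations of residuals of −0.005, −0.0025 and −0.00505 between groups. Figures were drawn with matplotlib 3.10.9.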

Results

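The data are guide counts from a pooled CRISPR knockout screen in HAP1 cells, with 2 samples each of the guide library, parental cells and SETD2-mutant cells after 12 doublings. SETD2 is the enzyme that trimethylates H3K36, a mark of transcribed gene bodies. The library samples held 38428425 and 34679351 counts, the parental samples 38197301 and 34003792, and the SETD2-mutant samples 25082426 and 33878004. Guides without a single count numbered 6 and 5 in the library, 89 and 116 in parental cells and 358 and 205 in SETD2-mutant cells, of 71626 guides. A negative log2 change of a gene means that cells carrying its guides became rarer. Across guides, which are not independent replicates, the change from library had a Pearson correlation of 0.913 between the parental replicates, 0.905 between the SETD2-mutant replicates and 0.776 to 0.782 across the lines.

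SETD2, the gene mutated by design, was examined first. In parental cells SETD2 (chromosome 3, 47016436 to 47164840) was depleted against library, with a mean log2 change of −1.12 (SE 0.308, 10 of 10 guides down) and replicate values of −1.08 and −1.17. In SETD2-mutant cells it was not called by edgeR and RRA, at −0.61 (SE 0.481, 5 of 10 guides down) with replicate values of −0.64 and −0.58, and 2 guides lay at −3.54 and −3.15 with the rest between −0.70 and 0.93. The adjusted p by edgeR and RRA was 0.000326 in parental and 0.739 in SETD2-mutant cells, where limma on gene means (−0.61, adjusted p = 0.000158) and summed counts per gene (−0.18, adjusted p = 0.00841) did call SETD2 depleted. Between the lines SETD2 was enriched by 0.50 (SE 0.216, 8 of 10 guides up, adjusted p = 0.00615 by edgeR and RRA). That call was lost without SETD2-mutant replicate 2, where the change was 0.47 and the adjusted p was 0.0777, the highest of its 22 alternatives. Guide counts do not read the SETD2 genotype itself, so they check the labels only through growth.

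SETD2-mutant against parental addresses which gene losses harm SETD2-mutant cells more than parental cells, and the title of the series points to NSD1. NSD1, which places the lower methylation states of H3K36, was depleted in SETD2-mutant relative to parental cells by −1.77 (SE 0.264, 10 of 10 guides down). NSD1 (chromosome 5, 177131798 to 177300213) was called in opposite directions in the lines. It was depleted in SETD2-mutant cells by −0.96 (SE 0.210), with replicate values of −0.95 and −0.98, a call that was lost at an RRA rank share limit of 0.1 (adjusted p = 1 by edgeR and RRA). In parental cells it was enriched relative to other genes by 0.80 (SE 0.159), with replicate values of 0.75 and 0.82. When samples were scaled on the dummyguide guides, the parental change shrank to 0.14 and the SETD2-mutant change stood at −1.815. The adjusted p by edgeR and RRA was 0.000161 between the lines, 0.00535 in SETD2-mutant and 0.00273 in parental cells. Apart from NSD1 and SETD2, edgeR with RRA called 0 of the measured H3K36 methyltransferases between the lines. Their changes were −0.29 for WHSC1L1 (NSD3), which summed counts per gene called depleted (adjusted p = 0.0340), −0.12 for SETMAR, −0.02 for ASH1L, which turned to 0.09 without parental replicate 2, and 0.15 for SMYD2, which turned to −0.04 with dummyguide scaling. NSD2 was not analysed here.

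**Figure D1:**
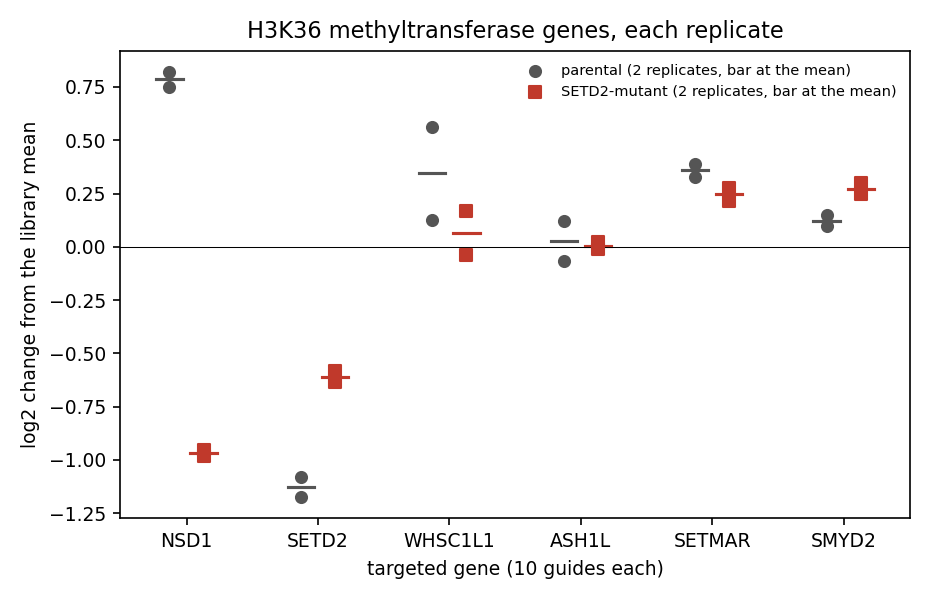
Log2 change from the library mean of the 6 measured H3K36 methyltransferase genes in each parental and SETD2-mutant replicate, with points for replicates and bars for their mean. NSD1 lay at 0.75 and 0.82 in parental and −0.95 and −0.98 in SETD2-mutant cells relative to other genes. With dummyguide scaling its values were 0.14 in parental and −1.815 in SETD2-mutant cells.

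In all, 91 genes were depleted and 73 enriched in SETD2-mutant relative to parental cells, of 7090. The depleted genes named here had the lowest RRA p and not the largest changes. HDAC3, the deacetylase of the NCoR and SMRT corepressors, stood at −1.79 (SE 0.235), MTF2, an accessory subunit of the PRC2 complex that methylates H3K27, at −1.71 (SE 0.25), PHF12, a subunit of a SIN3 deacetylase complex, at −1.51 (SE 0.281), and EP300, a histone acetyltransferase, at −1.07 (SE 0.119). CUL5 (chromosome 11, 108008898 to 108107761), the scaffold of a family of ubiquitin ligases, was depleted by −2.13 (SE 0.364), and KEAP1, the ubiquitin ligase adaptor that restrains NRF2, by −1.48 (SE 0.305). ACAD9, an assembly factor of respiratory complex I, stood at −1.52 (SE 0.173), IDH3B, a subunit of the citric acid cycle enzyme isocitrate dehydrogenase, at −1.31 (SE 0.115), SLC16A1, a lactate transporter, at −1.33 (SE 0.146) and NME6, of the nucleoside diphosphate kinase family, at −1.73 (SE 0.314). NPRL2, a subunit of the GATOR1 brake on mTORC1, stood at −1.51 (SE 0.265). The adjusted p by edgeR and RRA was 0.000161 for each of these genes except NPRL2, for which it was 0.000295, and at least 9 of 10 guides of each were down.

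The enriched genes named here had the lowest RRA p. Other enriched genes, among them TRIM28, LEO1 and SMARCB1, shared that p, and the named genes were taken from these by their larger changes. CAD (chromosome 2, 27217369 to 27243943), DHODH and UMPS, which carry out the de novo synthesis of pyrimidines, were enriched by 3.45 (SE 0.354), 1.74 (SE 0.0977) and 2.54 (SE 0.358). ATIC, which closes the purine ring, was enriched by 1.87 (SE 0.238). The mitochondrial citrate carrier SLC25A1 was enriched by 1.53 (SE 0.139), the inositol phosphate kinase ITPK1 by 1.5 (SE 0.242) and NAMPT, which salvages nicotinamide for NAD, by 1.44 (SE 0.234). All 10 guides of each of these genes were up, with an adjusted p of 9.33e-05 by edgeR and RRA. Of the 73 enriched genes, 33 were depleted against library in parental cells and not called in SETD2-mutant cells, 12 were depleted in both lines and 6 were enriched in SETD2-mutant cells and not called in parental cells. Of the 91 depleted genes, 31 were depleted in both lines, 26 were depleted in SETD2-mutant cells and not called in parental cells, 14 were enriched in parental cells and not called in SETD2-mutant cells, and 1, NSD1, was enriched in parental and depleted in SETD2-mutant cells.

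**Figure D2:**
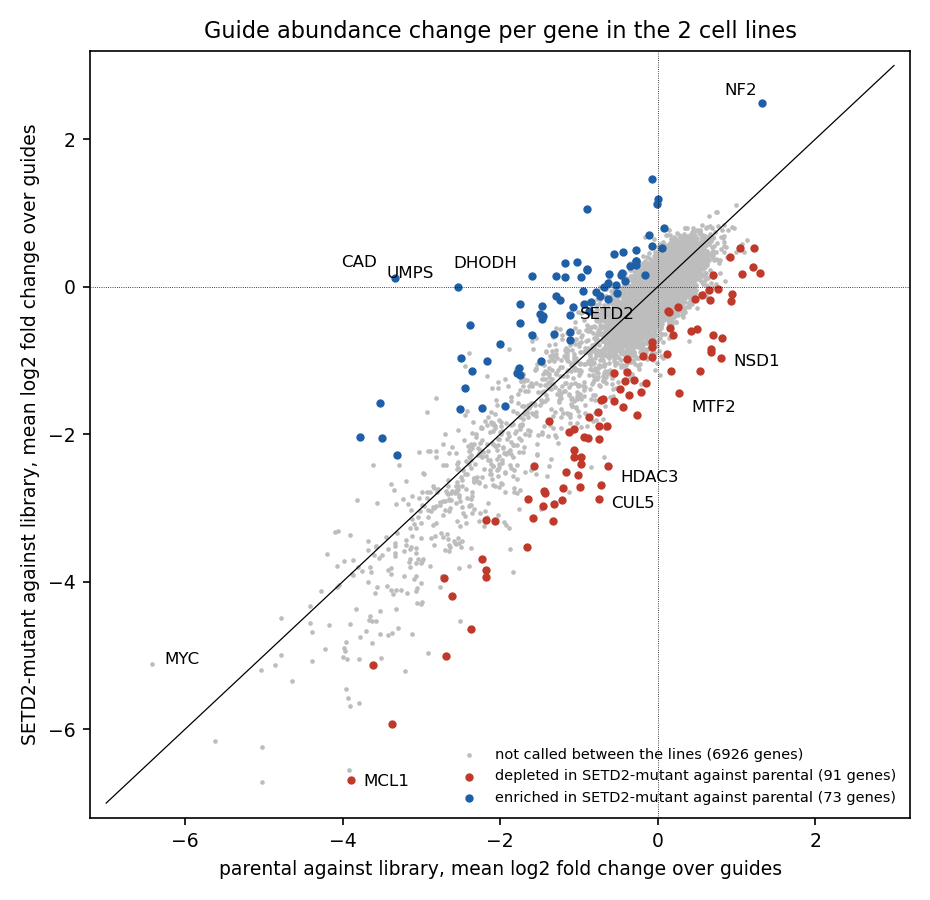
Log2 change from library of each of 7090 genes in parental cells (horizontal) and SETD2-mutant cells (vertical), with the 91 genes depleted and the 73 enriched between the lines in colour. NSD1 lies right of 0 and below it at 0.80 and −0.96, values relative to other genes. With dummyguide scaling its values were 0.14 in parental and −1.815 in SETD2-mutant cells.

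Among chromatin lists, 1 of 6 H3K36 methyltransferases was depleted and 1 enriched, the same numbers when adjusted over the list alone. Of 18 readers of H3K36 methylation, 3 were depleted (5 adjusted over the list alone) and 1 was enriched (1). The depleted readers were MTF2, the MSL complex subunit MSL3 at −0.97 and the acetyltransferase scaffold BRPF1 at −0.76, and the enriched reader was MORF4L1 at 0.68, which lies in a part of chromosome 15 whose uncalled genes had a median of −0.267 between the lines. Of 7 H3K36 demethylases, 0 were called and 1 was enriched when adjusted over the list alone, with KDM4C at 0.41 and an RRA p of 0.000566 before adjustment, and limma called 3 depleted and 1 enriched. PRC2 had 2 of 11 members depleted (3 adjusted over the list alone, with 2 enriched), MTF2 and the histone chaperone RBBP4 at −0.98. PRC1 had 1 of 21 depleted (1), the non-canonical subunit BCOR at −0.68, and NuRD had 2 of 13 depleted (2), RBBP4 and MTA1 at −0.71. In H3K4 methyltransferase complexes, 1 of 16 was depleted (1), the core subunit WDR5 at −1.22, and 2 were enriched (5), KMT2C at 0.43 and PAXIP1 at 0.54. For H3K9 methylation and HUSH, 2 of 12 were depleted (2), the methyltransferase SETDB1 at −1.12 and its partner ATF7IP at −0.95, and the corepressor TRIM28 was enriched by 1.16 (1). RNA polymerase II elongation had 1 of 12 depleted (1), the H3K79 methyltransferase DOT1L at −1.04, and 2 enriched (2), the PAF1 complex subunits LEO1 at 1.10 and CDC73 at 0.85. SWI/SNF had 1 of 16 depleted (1), ACTL6A at −2.33, and 1 enriched (1), SMARCB1 at 0.71. MOZ and HBO1 acetyltransferase complexes had 1 of 9 depleted (3), BRPF1.

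Respiratory complex I stood out among the metabolic and repair lists. Of its 15 measured genes, 8 were depleted, or 14 when adjusted over the list alone, with a median of −1.25. Examples were the subunits NDUFC2 at −1.85, NDUFA2 at −1.35 and NDUFA1 at −1.33 and the assembly factor FOXRED1 at −1.25. Camera gave the list an adjusted p of 3.19e-10, and adjusted p = 0.267 with an estimated correlation. The latter setting called 0 lists in each comparison, even ribosomal proteins in parental cells, with 47 of 48 genes depleted. A call lost with it therefore says little against a list. Cytosolic ribosomal proteins had a median of −0.64 with 1 of 48 depleted (1 adjusted over the list alone), RPL32 at −1.51. Of the 48 genes, 39 had a change below 0 and 9 above. Before adjustment 8 were depleted and 2 enriched by RRA, and limma called 29 depleted and 1 enriched. They had a camera adjusted p of 5.07e-05, and adjusted p = 0.452 with an estimated correlation. Essential genes, ribosomal ones among them, had a median loss of −3.388 in parental and −3.892 in SETD2-mutant cells. The lists were not tested at equal essential-gene dropout. Homologous recombination genes had a median of 0.23 with 0 of 17 called (7 enriched before adjustment and 7 by limma) and 6 enriched when adjusted over the list alone, a camera adjusted p of 0.000329, and adjusted p = 0.294 with an estimated correlation. Mismatch repair had a median of 0.20 with 0 of 6 called (3 enriched before adjustment and 5 by limma) and 3 enriched over the list alone, a camera adjusted p of 0.0368, and adjusted p = 0.452 with an estimated correlation.

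The remaining lists did not pass camera between the lines. mTORC1 and PI3K brakes had 2 of 3 depleted (2 adjusted over the list alone), NPRL2 and TSC1 at −1.67, each a restraint on mTORC1. Hippo pathway brakes had 1 of 7 enriched (1), NF2 at 1.16, and the Fanconi anaemia pathway had 2 of 12 enriched (3), FANCM at 0.59 and C19orf40 (FAAP24) at 0.62. RRA called 0 members, over all genes or over the list alone, among the 7 DNA methylation genes, 15 replication checkpoint and dNTP supply genes, 9 cell cycle brakes, 5 mTORC1 activators, 5 BCR-ABL signalling genes, 10 DNA replication genes, 5 cohesin genes, 4 Integrator genes and 8 peroxisome biogenesis genes. Before adjustment 8 of these 68 genes had an RRA p under 0.05 for depletion and 8 for enrichment, and limma on gene means called 19 depleted and 10 enriched. Of 10 spliceosome genes, 0 were called and 1 was depleted over the list alone, with 1 depleted before adjustment and 5 by limma. The camera direction was up where the median was negative for PRC2, RNA polymerase II elongation and BCR-ABL signalling, and the mean was negative where the median was positive for NuRD, H3K4 methyltransferase complexes and cohesin.

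**Figure D3:**
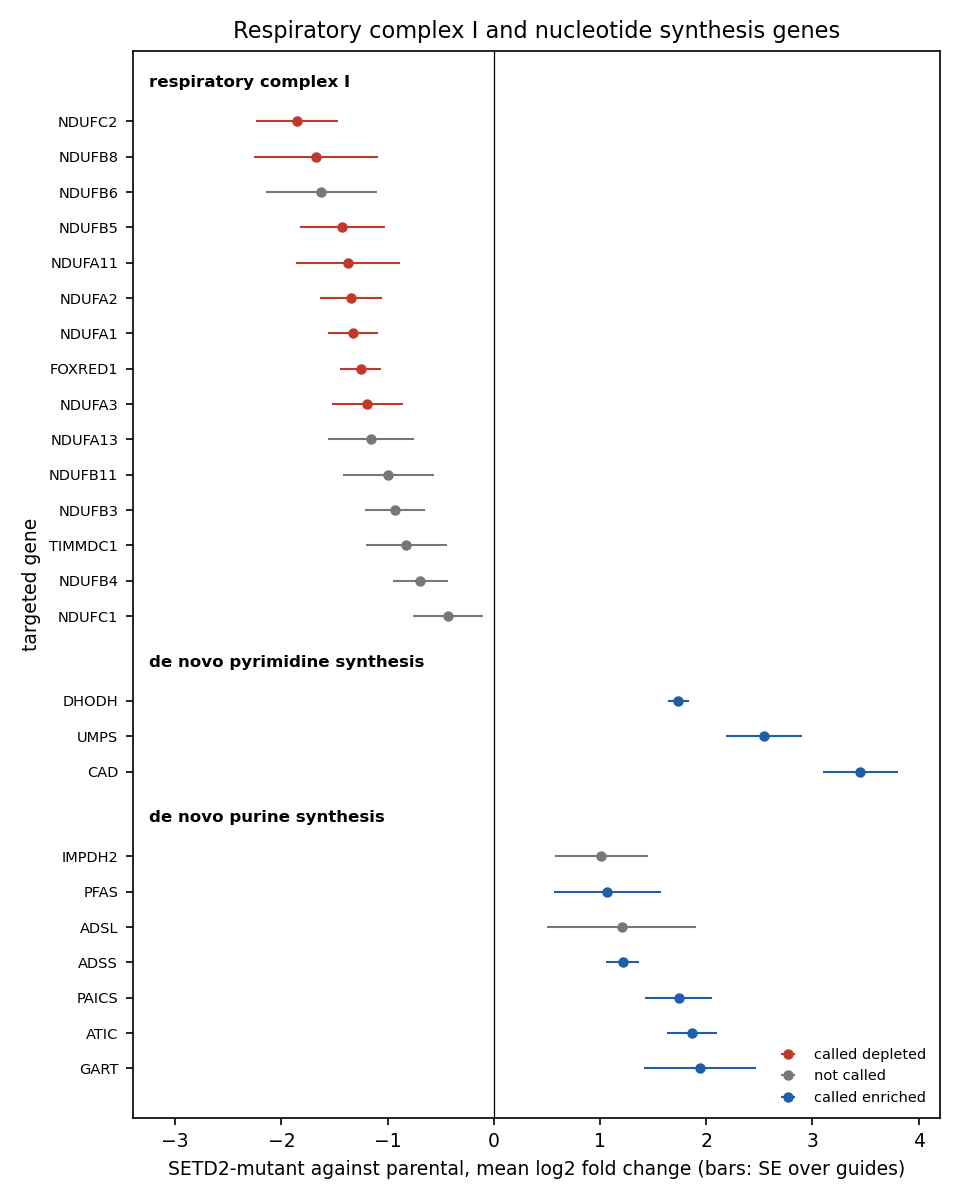
Mean log2 fold change between SETD2-mutant and parental cells of genes of respiratory complex I and of pyrimidine and purine synthesis, with bars for the SE over guides. Complex I genes lie below 0, with a median of −1.25, and CAD, UMPS and DHODH lie at 3.45, 2.54 and 1.74, and the nucleotide groups were chosen after their values were seen.

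The test between the lines was edgeR with RRA. Of all 7090 genes, 38.8% had both SETD2-mutant replicates below both parental replicates and 26.9% had them above. If the samples of the lines were interchangeable, 16.7% would fall in each direction. Guide differences shared by the replicates of a line can also raise these shares, so the excess does not measure gene effects. At equal essential-gene dropout in the lines there were 69 depleted and 116 enriched genes, so the balance of the directions depends on the scaling. Scaling on the dummyguide guides moved all genes by −0.19, and 13 of 91 depleted and 5 of 73 enriched genes lost their call, among them BRPF1 (adjusted p 0.0870), BCOR (0.0530), ACTL6A (0.0789), RPL32 (0.0789) and PAXIP1 (0.0606). Several list members also lost their call under other settings. With only the 2 groups fitted they were BRPF1 (0.1299), RBBP4 (0.204), BCOR (0.0565), WDR5 (0.157), ACTL6A (0.0762), FANCM (0.0752), C19orf40 (0.0946) and RPL32 (0.408). At equal essential-gene dropout they were BRPF1 (0.174), RBBP4 (0.0723), BCOR (0.0964), WDR5 (0.0832) and RPL32 (0.563), changed by −0.65, −0.62, −0.62, −0.77 and −0.91. Without guides depleted in both lines they were RBBP4 (0.196), WDR5 (0.108), ACTL6A (0.483) and RPL32 (0.592), changed by −0.68, −1.98, −1.51 and −0.68. At an RRA rank share limit of 0.1 they were MORF4L1 (0.176), PAXIP1 (0.292), ACTL6A (0.326), MTA1 (0.2997), NDUFC2 (0.243) and RPL32 (0.964), and with DESeq2 per guide BCOR (0.126) and ACTL6A (0.0749). BRPF1 lost its call as well with the replicate block (0.0694) and with summed library samples (0.111), and without library replicate 1, library replicate 2, parental replicate 1, parental replicate 2 or SETD2-mutant replicate 2 (0.117, 0.108, 0.120, 0.219 and 0.213). Without parental replicate 1 calls were lost for MORF4L1 (0.0975), RBBP4 (0.117), BCOR (0.292), PAXIP1 (0.112), C19orf40 (0.102) and RPL32 (0.0823), and without parental replicate 2 for MORF4L1 (0.0665), PAXIP1 (0.0691), ACTL6A (0.0591), MTA1 (0.220), FANCM (0.116) and RPL32 (0.0963). Without SETD2-mutant replicate 1 they were lost for MORF4L1 (0.0978), MSL3 (0.0629), RBBP4 (0.447), BCOR (0.103), PAXIP1 (0.366), ACTL6A (0.282), MTA1 (0.224) and C19orf40 (0.0882). Without SETD2-mutant replicate 2 they were lost for MSL3 (0.0627), RBBP4 (0.325), FANCM (0.0670), C19orf40 (0.0915) and RPL32 (0.210), with all values in parentheses here being adjusted p by RRA.

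Parental against library shows which genes HAP1 cells needed over the screen. In total, 702 genes were depleted and 79 enriched. MYC, the growth-promoting transcription factor, fell the furthest of the named genes, by −6.42 (SE 0.728). ATP6V0C, a subunit of the proton pump of lysosomes, followed at −5.62 (SE 0.995), then ribosomal proteins RPL12 at −5.04 (SE 0.931), RPS4X at −5.03 (SE 0.671), RPL23A at −5.02 (SE 0.811), RPL7 at −4.78 (SE 0.616), RPS23 at −4.42 (SE 0.747) and RPS19 at −4.28 (SE 0.482). RFC3, a subunit of the replication clamp loader, stood at −4.64 (SE 0.580) and HSPA9, a mitochondrial chaperone, at −4.08 (SE 0.578). Enriched genes, relative to other genes, included the Hippo pathway activator NF2 at 1.33 (SE 0.306), GATAD1 at 1.22 (SE 0.110), TP73 at 1.14 (SE 0.0824), the kinase CDK5 at 1.07 (SE 0.121), the H3K4 demethylase KDM5C at 1.05 (SE 0.230) and the PI3-kinase regulator PIK3R1 at 1.00 (SE 0.166). These 6 stayed above 0 with dummyguide scaling, at 0.33 to 0.67. The adjusted p by edgeR and RRA was 1.27e-05 for each of these depleted genes and 0.000222 for each enriched gene.

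In parental cells most members of several DNA repair and replication lists were depleted. For the homologous recombination, Fanconi anaemia, DNA replication and replication checkpoint lists camera gave adjusted p = 0.0694 with an estimated correlation, and for the other lists it called below adjusted p = 0.0694 to 0.274 with an estimated correlation. Mismatch repair had 1 of 6 genes depleted (1 adjusted over the list alone) and a median of −0.25, with a camera adjusted p of 0.232, and adjusted p = 0.361 with an estimated correlation. All 17 homologous recombination genes were depleted, with BRCA1 at −2.79 and BRCA2 at −2.24, as were all 12 Fanconi anaemia genes, with FANCI at −2.26, all 10 DNA replication genes, with PCNA at −3.68, and 14 of 15 replication checkpoint and dNTP supply genes, with WEE1 at −3.07 and ATR at −2.65. Ribosomal proteins were depleted in 47 of 48 cases with a median of −3.55, spliceosome genes in 10 of 10, Integrator in 4 of 4, cohesin in 4 of 5 (5 adjusted over the list alone) and mTORC1 activators in 4 of 5, with RHEB at −3.19. Of RNA polymerase II elongation genes 10 of 12 were depleted (11 over the list alone), of complex I 8 of 15 (12), of H3K4 methyltransferase complexes 9 of 16 (11) and of PRC2 5 of 11 (6), with SUZ12 at −1.71 and EZH2 at −0.97. H3K36 demethylases had 2 of 7 depleted (2), KDM2A at −1.71 and KDM8 at −2.34, and MOZ and HBO1 complexes 1 of 9 (2), KAT7 at −1.52. For the other lists named here the count adjusted over the list alone was the same. ATM, the DNA damage kinase, was depleted at −1.37. SETDB1 at 0.93 and ATF7IP at 1.21 were enriched relative to other genes and stayed above 0 with dummyguide scaling, at 0.27 and 0.55.

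The test was edgeR with RRA for genes and camera for lists. Camera called 15 of 28 lists, those with counts above except mismatch repair, and 0 with an estimated correlation, where the lowest adjusted p = 0.0694 with an estimated correlation and 9 lists had an unadjusted p under 0.05, while fry called 25. Scaling on the dummyguide guides moved all genes by −0.66, 87 of 702 depleted and 33 of 79 enriched genes lost their call, and 41 of 79 enriched genes stayed above 0, so enrichment here is relative to the bulk of guides.

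SETD2-mutant against library asks the same of the mutant cells, in which 641 genes were depleted and 79 enriched. RPS4X at −6.72 (SE 0.620), RPL23A at −6.24 (SE 0.953), RPL34 at −5.69 (SE 0.772) and RPL30 at −5.57 (SE 1.10) encode ribosomal proteins. MCL1, which blocks apoptosis, stood at −6.69 (SE 0.987), ATP6V0C at −6.16 (SE 1.15), NHP2L1, a protein of spliceosomal and nucleolar particles, at −5.93 (SE 0.895), the mitotic kinase PLK1 at −5.45 (SE 0.956), RFC3 at −5.34 (SE 1.04) and TIMM23, a channel for mitochondrial protein import, at −5.21 (SE 0.815). Enriched relative to other genes were NF2 at 2.49 (SE 0.178), SLC25A1 at 1.46 (SE 0.0850), the pyruvate dehydrogenase subunit PDHB at 1.12 (SE 0.183), PIK3R1 at 1.10 (SE 0.202) and the receptor MC4R at 0.83 (SE 0.135), of which MC4R turned to −0.02 with dummyguide scaling. The adjusted p by edgeR and RRA was 1.61e-05 for each of these depleted genes and 0.000253 for each enriched gene.

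Complex I was depleted in 14 of 15 genes in SETD2-mutant cells (15 adjusted over the list alone), with a median of −2.40, NDUFA1 at −2.77 and NDUFA11 at −2.80. For it camera gave adjusted p = 0.0737 with an estimated correlation, and for the lists that follow adjusted p = 0.0737 to 0.259 with an estimated correlation. Homologous recombination genes were depleted in 15 of 17 cases, Fanconi anaemia genes in 11 of 12 (12 over the list alone), DNA replication genes in 10 of 10, replication checkpoint and dNTP supply genes in 13 of 15 and spliceosome genes in 10 of 10. Ribosomal proteins were depleted in 47 of 48 cases with a median of −4.11. H3K4 methyltransferase complexes had 7 of 16 depleted (9), with WDR5 at −3.94, RNA polymerase II elongation 7 of 12 (10), PRC2 3 of 11 (4), with MTF2 at −1.44, MOZ and HBO1 complexes 3 of 9 (5), cohesin 4 of 5, Integrator 3 of 4 (4) and mTORC1 activators 4 of 5. Where none is given, the count adjusted over the list alone was the same. ACTL6A, a subunit shared by SWI/SNF and other complexes, stood at −5.01.

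The same tests were used, and camera called 14 of 28 lists, those with counts above, and 0 with an estimated correlation, where the lowest adjusted p = 0.0737 with an estimated correlation and 9 lists had an unadjusted p under 0.05, while fry called 27. Scaling on the dummyguide guides moved all genes by −0.85, 131 of 641 depleted and 46 of 79 enriched genes lost their call, and 9 of 79 enriched genes stayed above 0, and without SETD2-mutant replicate 1 the number enriched was 50.

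The dropout profiles of the lines overlapped widely. Of the depleted genes, 559 were called in both lines, where 63.5 would be shared if the calls were independent, and 25 were enriched in both relative to other genes, where 0.88 would be. Genes that were called in 1 line alone are not shown to differ unless the direct comparison called them, as it did for CAD, UMPS and DHODH, which were called depleted in parental cells alone. Across 7090 genes, which are not independent replicates, the changes had a Pearson correlation of 0.924 and a Spearman correlation of 0.811. In 20 simulations of unchanged cell lines against the same library samples the Pearson correlation was at most 0.0401. The simulated cells were drawn around the mean of these library samples, so a correlation near 0 was built in. It does not measure how much of the observed correlation the shared library samples add. The simulations also shared 0 calls, but unchanged genes are seldom called, so this does not measure the overlap that the library samples add. The 2 library samples serve both comparisons and were not divided between them.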

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

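The tests of the dummyguide median, the chromosome 15 segment, the dummyguide p-values, essential-gene loss and the number of SETD2-mutant lines were chosen only after the result was seen.

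Several genes changed from library by different amounts in the lines, by the direct edgeR and RRA test of SETD2-mutant against parental. The difference was 0.50 for SETD2, −1.77 for NSD1, −2.13 for CUL5, −1.79 for HDAC3, −1.73 for NME6, −1.71 for MTF2, −1.52 for ACAD9, −1.51 for PHF12, −1.48 for KEAP1, −1.33 for SLC16A1, −1.31 for IDH3B, −1.07 for EP300 and −1.51 for NPRL2. It was 3.45 for CAD, 2.54 for UMPS, 1.87 for ATIC, 1.74 for DHODH, 1.53 for SLC25A1, 1.5 for ITPK1 and 1.44 for NAMPT. By camera with the preset correlation the lines also differed for homologous recombination (median 0.23), mismatch repair (0.20), respiratory complex I (−1.25) and cytosolic ribosomal proteins (−0.64). With an estimated correlation camera did not call these lists. That setting called 0 lists in each comparison, even ribosomal proteins in parental cells, with 47 of 48 genes depleted (camera adjusted p = 0.0694). Its lack of a call therefore says little against a list. The ribosomal genes belong to 59 essential genes whose median loss was −3.388 in parental and −3.892 in SETD2-mutant cells. The lists were not tested at equal essential-gene dropout.

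Guides of nucleotide synthesis genes such as CAD, UMPS, DHODH and ATIC were lost less in SETD2-mutant cells. Weaker selection or fewer divisions in those cultures is argued against, since the median loss of 59 ribosomal, spliceosome and proteasome genes was larger in SETD2-mutant cells in each pair of replicates, with a lowest ratio of 1.144. A copy number change shared by their chromosome segments is argued against as well. The 205 genes within 2 Mb of the 12 called nucleotide and folate genes had a median change of 0.023 (95% interval −0.013 to 0.0545). This median pools all the segments, so a copy number change around a single gene stays open. The labels name 1 SETD2-mutant genotype and no number of lines, so the SETD2 genotype and any other difference between the lines cannot be told apart.

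Many guides differed between the lines beyond the spread of their replicates, 39.3% at an unadjusted p under 0.05. The dummyguides carry no gene name, and whether they share a target is not stated. Of them, 42.0% also differed (exact 95% interval 32.2 to 52.3%), but as a set they moved up by a median of 0.24. With that shift taken out by dummyguide scaling 32.0% differed (23 to 42.1%). This interval lies above the bound of 10% for no such differences, but includes the bound of 25% for them. Guide-specific differences set in each line before it was divided into replicates are therefore not argued against, and stay open. Single genes were called between the lines, but whether gene effects account for the many differing guides stays open too. The intraclass correlation of guides within genes was 0.105 (95% interval 0.0956 to 0.117), between the bounds of 0.1 and 0.2 set beforehand, and 0.0568 among uncalled genes.

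The guides labelled dummyguide, used in no comparison, gained against library, with a median log2 change of 0.69 in parental and 0.88 in SETD2-mutant cells. Dropout of other guides alone is argued against, since the dummyguide median exceeded that of guides of uncalled genes by 0.608 in parental (95% interval 0.556 to 0.713) and by 0.780 in SETD2-mutant cells (0.728 to 0.889). Their lower library abundance is argued against too, since 0% of 10000 sets of gene guides matched on abundance had a mean as high, with highest means of 0.132 and 0.177 against 0.671 and 0.860. A cost of DNA cutting borne by guides with a genomic target may account for it, if dummyguides lack a target, which the labels do not say. In that case guides that cut more copies should lose more, and uncalled genes between 60 and 90 Mb of chromosome 15, a segment that HAP1 is known to carry as an extra copy and that was noticed in these data before the test was set, lay below those of the rest of the chromosome by −0.452 in parental and −0.679 in SETD2-mutant cells.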

How the results depend on the processing

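Scaling on dummyguide counts (geometric mean or sum), summing the library samples and leaving out guides depleted in both lines were chosen only after the result was seen. DESeq2 size factors, library totals, DESeq2 per guide and the count filters kept every gene count within 1.5 times its reported value. So did the rank share limit, fitting 2 groups, summed library samples and the replicate block. The block gave 88 depleted and 84 enriched genes between the lines, 710 and 84 in parental, and 642 and 84 in SETD2-mutant cells. Similar counts hid lost calls. Between the lines, fitting only the 2 groups lost 28 of 91 depleted and 9 of 73 enriched genes. A rank share limit of 0.1 lost 22 and 10 of these, and 192 of 641 depleted genes in SETD2-mutant cells against library. Summed counts per gene called 1503 depleted and 1417 enriched genes between the lines, 2149 and 2092 in parental and 2320 and 2138 in SETD2-mutant cells, and limma on gene means called 1561 and 895, 2217 and 1674, and 2693 and 1687. In the simulation, summed counts called 48.5% of unchanged genes when guide differences were shared within a line. Equal essential-gene dropout gave 116 enriched genes between the lines, and dummyguide scaling 45 in SETD2-mutant cells against library. The cause of these 2 changes was not tested. Leaving out 1 sample gave 63 to 89 depleted and 68 to 81 enriched genes between the lines, and 50 to 86 enriched genes in SETD2-mutant cells against library, with 50 without SETD2-mutant replicate 1. A group left with 1 sample was assumed to vary like the others. Camera with an estimated correlation called 0 lists in each comparison and fry called 17 between the lines, 25 in parental and 27 in SETD2-mutant cells. With an estimated correlation 3, 9 and 9 lists had an unadjusted p under 0.05. Ribosomal proteins, with 47 of 48 genes depleted in parental cells, were also not called by it, so it had little power here.

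For single named genes, 54 planned and 10 added results lost a call and 12 gained one with the sign kept, among them the depletion of NSD1 in SETD2-mutant cells at a rank share limit of 0.1 (adjusted p = 1 by edgeR and RRA). Reversed signs were all in uncalled genes except MC4R, at −0.0237 in SETD2-mutant cells with dummyguide scaling. With that scaling, SMYD2 was −0.0402 between the lines, WHSC1L1 −0.28, ASH1L −0.62, SETMAR −0.30 and SMYD2 −0.52 in parental cells, and WHSC1L1 −0.76, ASH1L −0.83, SETMAR −0.60 and SMYD2 −0.56 in SETD2-mutant cells. With summed counts, WHSC1L1 was −0.0736 and ASH1L −0.0409 in SETD2-mutant cells. Leaving out 1 sample, ASH1L ranged from −0.103 to 0.0853 between the lines and from −0.0677 to 0.12 in parental cells, with its sign turned without parental replicate 2. In SETD2-mutant cells WHSC1L1 ranged from −0.0411 to 0.17, turned without SETD2-mutant replicate 1, and ASH1L from −0.0113 to 0.021, turned without SETD2-mutant replicate 2. The cause was not tested. Scaling on summed dummyguide counts, tried before the geometric mean, shifted all genes by −0.15 between the lines, −0.78 in parental and −0.92 in SETD2-mutant cells. It left 28 and 9 of 79 enriched genes above 0 in the lines, and put NSD1 at 0.03 in parental and −1.888 in SETD2-mutant cells. Scaling on olfactory receptor guides was not run, since the table holds 0 such genes. Small effects are limited by differences between guides and lines rather than by depth, since the spread of guide differences between the lines was 0.741 (SD, log2) where replicates gave 0.356.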

Other observations

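The gene groups and the chromosome 15 region below were chosen only after the result was seen, from tables of all genes and of medians along each chromosome in all 3 comparisons.

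The SAGA coactivator complex had 7 of 14 members enriched in SETD2-mutant relative to parental cells. Its deubiquitinase USP22 stood at 1.36 and TAF6L, TAF5L, TADA1 and TADA2B at 1.13, 1.05, 1.05 and 1.00, and 8 of the 14 were depleted against library in parental and 4 in SETD2-mutant cells. Purine synthesis had 5 of 7 enriched, with GART at 1.94 and PAICS at 1.74, and all 7 were depleted in parental cells and 5 in SETD2-mutant cells. Of 3 pyrimidine synthesis genes, all were enriched between the lines and depleted in parental cells, and 0 were called in SETD2-mutant cells, with a median of 0.12. Folate one-carbon enzymes had 4 of 10 enriched, with MTHFD1 at 1.54 and FPGS, which retains folates in the cell, at 1.26. Camera gave an adjusted p of 0.000418 for SAGA, 6.51e-07 for purine, 2.77e-05 for pyrimidine and 5.95e-05 for folate genes, and adjusted p = 0.0568 with an estimated correlation for each of them.

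Mitochondrial enzymes moved both ways. Pyruvate dehydrogenase had 3 of 5 members enriched, PDHA1 at 1.18, PDHB at 1.13 and DLAT at 0.71. Cytochrome c oxidase had 3 of 15 depleted, with COX4I1 at −1.62. In the citric acid cycle 3 of 15 were depleted, among them IDH3A at −1.54 and IDH3B at −1.31, and 3 were enriched, SDHB at 1.16, MDH2 at 0.78 and SDHD at 0.32. The camera adjusted p was 0.00559, 0.00101 and 0.162 for these lists, and adjusted p = 0.177, 0.0568 and 0.283 with an estimated correlation.

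On chromosome 15 between 60 and 90 Mb, 66 genes called in no comparison had a median change from library of −0.438 in parental and −0.712 in SETD2-mutant cells, and of −0.267 between the lines. The other 97 uncalled genes of the chromosome had medians of 0.0141, −0.0333 and 0.0011. The lowest medians of 250 other windows of 30 Mb were −0.201, −0.301 and −0.164, and the highest were 0.295, 0.33 and 0.264. The last, on chromosome 18 between 20 and 50 Mb, was about as large between the lines as that of the segment. Inside the segment CSK, IDH3A, PIAS1 and USP3 were depleted and MORF4L1 was enriched between the lines. Guide IDs carry a class, whose meaning is not stated, and of the 46 genes of the class CTRLe 45 were depleted in each line, against 4 of 73 in parental and 1 of 73 in SETD2-mutant cells for the class CTRL.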
